A study of Mus musculus with 2 samples.

How the data were processed

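Single-cell RNA was measured in 2 libraries of sorted mouse aortic cells, one per group. Per the labels' protocols, whole aortas without perivascular fat were digested with collagenases, hyaluronidase and DNase, cells were sorted by flow cytometry, and 3' libraries were made with the second version of the 10x Chromium chemistry, in which each captured transcript carries a cell barcode and a unique molecular identifier (UMI). The deposited matrices hold counts, that is, whole numbers of UMIs per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger, Seurat and the mm10 genome build. Their versions, and the filter by which barcodes were called cells, are not given in the sources used here. Both matrices list the same 27998 genes. The CD45+ library has 3781 barcodes and the foam library 809, the same numbers as the cell counts stated in the study's design text.

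Cells with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes were kept, and doublets predicted by Scrublet (as implemented in scanpy 1.11.5, expected rate 0.06) were removed. Scrublet marked 0 of 3781 barcodes in the CD45+ library and 2 of 809 in the foam library, so doublets were in practice not removed; an alternative without the 5% of cells with the most UMIs was added after seeing the data. Each library was clustered alone with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. The genes of the fixed lists were left out of the variable genes, so that none of them defined a cluster. Genes that vary with them could stay in, and list genes such as Tnf and Ifit3 still led CD45+ clusters. List values are therefore not independent of the clustering.

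Clusters were named from marker lists fixed before the data were examined, of which 181 of 188 markers were in the gene names; the rule that scores them was written with the data at hand. A marker counted as high in a cluster when at least 25% of its cells held a UMI and its level was at least 0.25 of that in the highest cluster of the library. A class needed at least 3 high markers and a share of at least 0.5 of its list, and the class with the largest share gave the name. The name was withdrawn when another class had more markers than its own among the 10 leading genes by fold. That fold was taken against cells outside the class, because most CD45+ cells were macrophage-like and a macrophage cluster set against the rest of its library is set mainly against other macrophages. Against the rest of the library, 4 macrophage-like CD45+ clusters were led by 1 marker of another class and none of their own; comparisons were repeated without them. Foamy-like and resident-like are subsets of macrophage-like cells with a share of at least 0.5 of their own markers. The name was withdrawn from 2 foam library clusters, one of which (cluster 10, 81 cells) had macrophage as its class by marker share; comparisons were repeated with its cells.

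There is 1 library per group, pooled from 6 mice, so no test between groups was possible and no p-value is given. UMIs were summed over the cells of a pool and given as counts per 1000000 UMIs of that pool (CPM). Sums carry exact Poisson 95% intervals, shares exact binomial (Clopper-Pearson) 95% intervals, and ratios of 2 pools exact conditional 95% intervals. All of these cover counting error only, not variation between mice, dissections or libraries. Those of sums and ratios also leave out variation between the cells of a pool. A gene was measured when it reached 50 CPM and 20 UMIs in at least one of the pools compared. Log2 ratios were taken after adding 0.5 UMI to each sum. Where a sum was 0, the bound was computed with 3 counts over the pool. For each of 19 gene lists fixed beforehand, the median log2 ratio over measured members is given with an interval from 1000 Poisson redraws, and with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test. No member of the sterol synthesis list was measured in any of the 4 comparisons, so 18 lists have values. Genes are named by a rule set beforehand. Between libraries these are the 12 highest and 12 lowest log2 ratios, without mitochondrial, ribosomal protein, unnamed, genotype target and sex-linked genes. Within a library they are the 12 highest and 12 lowest among list genes. Apoe, Ldlr, Trem2, Cd9, Il1b and Tnf are always given. Gene coordinates are from GENCODE M21 on the mouse build GRCm38, which mm10 also denotes.

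The computation of ratios was tested on simulated counts with 200 genes changed by known folds. Of the 50 genes per fold, 100% had the right direction in each comparison. The intervals covered the true ratio for 90% to 100% of the genes at each fold. Median log2 ratios were somewhat low, from 0.82 to 0.98 for a true fold of 2, since ratios are of shares of a total. Clustering and naming were tested in 2 ways. In cells drawn from their cluster's mean profile, the clusters returned (adjusted Rand index 0.997 to 1 in the CD45+ library), but the class names of only 85.3% to 92.8% of CD45+ cells did: the dendritic cell cluster and the 30 smooth muscle-like cells lost their names in each of 3 draws, and a macrophage cluster in 1. In the foam library 100% of cells kept their class there. This simulation spreads the transcripts of a few odd cells over a whole cluster. A second simulation, chosen after that result, redrew each cell around its own counts. There 96.4% to 97.3% of CD45+ cells and 83.8% to 87.5% of foam library cells kept their class, while the adjusted Rand index was 0.509 to 0.535 and 0.601 to 0.645. Of CD45+ cells outside the macrophage class, 13.0% to 13.9% were then called macrophage-like, and 83.5% to 91.1% of foamy-like cells kept that name. In the CD45+ library, whether classes or clusters returned better thus differed between the 2 simulations.

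Other settings tried were other cell filters (200 genes and 20% mitochondrial, 1000 genes and 5%), doublets kept, Leiden resolutions 0.6 and 1.6, list genes kept for clustering, another seed, median-ratio scaling, equal weight per cell, measurement minimums of 20 and 100 CPM, and cells thinned to 2000 UMIs. Added after seeing the data were the omission of the 4 clusters above, the inclusion of cluster 10, subtraction of free RNA, removal of the cells with the most UMIs, removal of proliferating clusters, and a split of the cells against which foamy-like macrophages were compared. Analyses used numpy 2.4.6, scipy 1.17.1 and Python 3.11.15.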

Results

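Cells of atherosclerotic mouse aorta were profiled in 2 single-cell libraries. The CD45+ library holds live leukocytes, sorted on the pan-leukocyte surface protein CD45, from 6 Ldlr-deficient mice fed western diet for 12 weeks. The foam library holds lipid-laden cells, sorted on high signal of the neutral lipid dye BODIPY and high side scatter with no CD45 gate, from 6 Apoe-deficient mice fed the diet for 27 weeks. Both strains lack a gene of lipoprotein handling and develop atherosclerosis on this diet. Genotype, weeks of diet, sort and library differ together between the groups, so a difference between the libraries cannot be assigned to any one of them, and with 1 library per group none has a replicate check. The files hold 37203855 UMIs in 3781 CD45+ barcodes (median 8687 per barcode) and 18170719 UMIs in 809 foam barcodes (median 20130). After filtering, 3745 and 751 cells were analysed. Intervals in brackets are 95% intervals of counting error only.

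The targeted genes were read first. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand, GRCm38), which encodes the lipoprotein ligand apolipoprotein E, stood at 26139 counts per 1000000 UMIs of the pool (CPM; 26087 to 26191) in the CD45+ library and at 33.3 (30.6 to 36.1) in the foam library, a ratio of 786 (725 to 854). Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919, plus strand), the low-density lipoprotein receptor, gave 27 UMIs in the CD45+ library, or 0.728 CPM (0.480 to 1.06), and 64 in the foam library, or 3.64 CPM (2.81 to 4.65). Ldlr was near the detection limit in both. Within macrophage-like cells alone Apoe stood at 29933 CPM in the CD45+ and 39.4 in the foam library, so its transcript was largely absent from the latter. The labels do not say which part of either gene was disrupted. For Ldlr, a 3' tag outside that part would check nothing.

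The first question was which cells each sort contained. Macrophage-like cells made up 85.3% (84.1% to 86.4%) of the CD45+ library, 3193 of 3745 cells in 12 clusters. The rest were dendritic cells of the monocyte-derived or conventional DC2 type (6.36%), T cell-like cells (2.91%), monocyte-like cells (2.83%), conventional DC1-like cells (1.84%) and 30 smooth muscle-like cells (0.801%). Among the macrophages, 236 cells in 1 cluster carried the foamy markers, which is 7.39% (6.51% to 8.35%) of macrophage-like cells, and 1510 cells in 5 clusters carried resident markers such as Lyve1 and Folr2. The remaining 1447 carried neither set. Separate clusters of these were led by Tnf, Ccl4 and Cxcl10, by Il1rn, Ptgs2 and Il1b, or by the interferon-induced genes Ifit3 and Rsad2. The others were led by Ccr2, Tppp3 and Fn1, by Asb2, Apbb2 and Nes, or, in a proliferating cluster, by Ccnb1 and Aspm. The foamy-like share depended on the clustering and reached 16.3% at Leiden resolution 0.6. A class check against the rest of the library would leave 46.0% of CD45+ cells as macrophage-like, since 4 clusters had a marker of another class and none of their own among their leading genes.

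In the foam library, macrophage-like cells made up 51.7% (48.0% to 55.3%), 388 of 751 cells, and smooth muscle-like cells, with the contractile genes Acta2 and Myh11, 19.7% (16.9% to 22.7%). Fibroblast-like (5.59%), endothelial-like (2.66%) and mesothelial-like cells (1.07%) were also present, and 145 cells (19.3%) in 2 clusters stayed unnamed. One of these, cluster 10 with 81 cells, had all 12 macrophage markers high and lost the name because monocyte markers such as Ccr2 were among its leading genes; with it, the macrophage-like share was 62.5%. With other settings the share ranged from 43.4% with another clustering seed to 60.7% with the strict cell filter, which is wider than its interval. With the strict filter the smooth muscle-like share was 3.18%, 19 of 598 cells in place of 148 of 751. Fibroblast-like cells were then 110 in place of 42, so part of that drop can be a change of name. All 5 clusters named macrophage-like carried the foamy markers and none the resident set, while cluster 10 had 4 of 8 resident markers high. Foamy markers were, however, also detected in smooth muscle-like cells, from 6.13% of the macrophage level for Mmp12 to 49.3% for Fabp4 and 57.6% for Cd9. The sorts differ in their gates, so shares are not compared between the libraries.

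**Figure D1:**
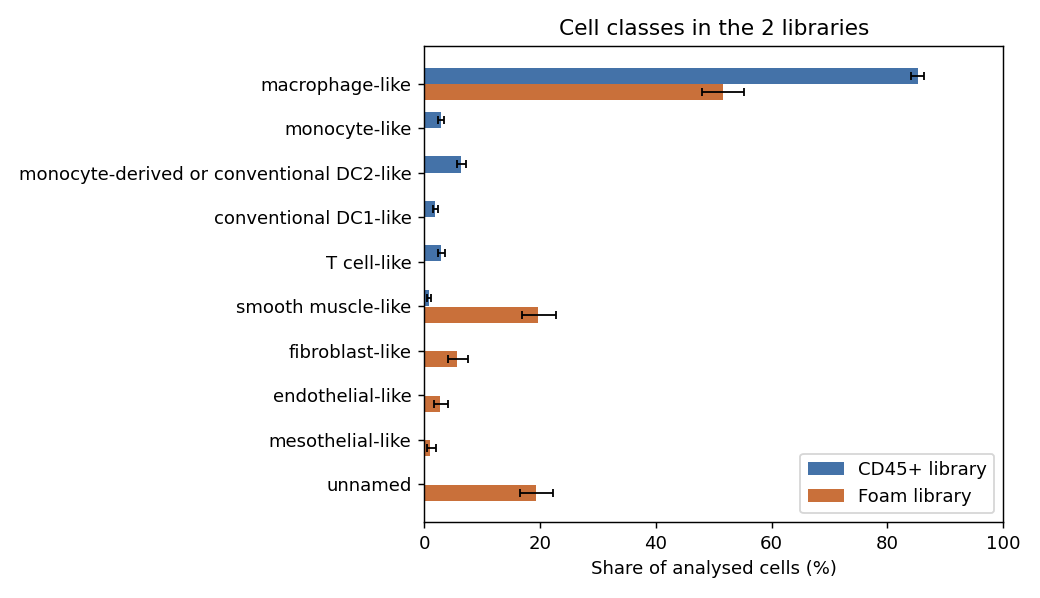
Share of analysed cells (x axis, %) by cell class (y axis) in the CD45+ library (blue) and the foam library (orange); bars are shares of cells and black lines exact binomial 95% intervals, which cover counting error only. Macrophage-like cells made up 85.3% of the CD45+ and 51.7% of the foam library.

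The next comparison asked how foamy-like macrophages differed from the other macrophages of the same CD45+ library. Genes of the cholesterol efflux and LXR target list and of lipid storage stood higher in foamy-like cells. That list, called efflux genes below, mixes exporters with other LXR targets such as Lpl and Scd2. Of its 9 measured genes, 5 were at least 2-fold higher and 0 at least 2-fold lower. They include Lpl, lipoprotein lipase, at 941 against 98.6 CPM (ratio 9.54, 9.07 to 10.03), Apoc1 (9.27, 7.72 to 11.1), Scd2 (7.64, 6.48 to 9.01) and Nr1h3, which encodes the sterol-sensing receptor LXR alpha (6.85, 5.61 to 8.37). The lipid droplet list had 3 of 5 members 2-fold higher. Plin2, a droplet coat protein, stood at 1267 against 297 (4.27, 4.12 to 4.42), and Soat1, which esterifies cholesterol, at 153 against 42.3 (3.62, 3.28 to 4.01). Of 20 lysosomal genes 12 were 2-fold higher, among them the proton pump subunit Atp6v0d2 (19.6, 16.8 to 22.9) and the protease Ctsd (7.29, 7.16 to 7.42). The list medians were 2.30 (2.20 to 2.40), 1.86 (1.71 to 1.99) and 1.35 (1.28 to 1.42) on the log2 scale, at percentiles 100, 99.98 and 100 of matched random lists. At Leiden resolution 0.6, where 527 cells were foamy-like, they were 0.41, 1.41 and 0.83. Single genes with higher levels also included Cd5l (28.7, 24.2 to 34.2), Arg1 (30.4, 23.7 to 39.4, a log2 ratio of 4.92 that was 0.82 without the cells with the most UMIs), Adam8 (10.9, 9.36 to 12.6), Cd300lf (6.88, 5.83 to 8.12), Tnfaip2 (5.34, 4.91 to 5.81) and Tgm2 (5.12, 4.66 to 5.63).

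Inflammatory lists stood lower in foamy-like cells than in all other macrophages, and how much lower depended on which macrophages they were set against. Of 8 measured proinflammatory genes, 6 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -1.54 (-1.70 to -1.46) at percentile 0.01; at Leiden resolution 0.6 the median was -0.84. Il1b stood at 234 against 1050 CPM, a ratio of 0.223 (0.208 to 0.238), and Tnf at 63.0 against 209 (0.301, 0.264 to 0.343). Against resident-like macrophages alone the proinflammatory median was -0.46 (-0.56 to -0.26, percentile 6.54) with 1 of 7 members 2-fold lower, and the direction of Il1b was the opposite, 234 in foamy-like against 190 in resident-like cells. Against the macrophages that carried neither marker set the median was -2.02 (-2.18 to -1.94), and Il1b stood at 1751 there. The split was added after seeing the data. Chemokines kept a lower median in both parts, -1.72 against resident-like cells and -1.57 against the others. Genes induced by tissue dissociation stood lower as well: 10 of 15 immediate early genes were at least 2-fold lower in foamy-like cells (median -1.42, and -1.46 against resident-like cells), such as Hspa1b (0.102, 0.085 to 0.121) and Hspa1a (0.133, 0.126 to 0.141), and the cells had been digested at 37 degrees before sorting.

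Other lists in the same comparison were as follows. Of 14 chemokines 10 were 2-fold lower (median -2.29), including Ccl24 (0.049), Pf4 (0.116) and Cxcl10 (0.157). NF-kB feedback genes had 9 of 13 lower and 1 higher (median -1.32), with Nfkbiz at a ratio of 0.160. Of 9 interferon response genes 8 were lower (median -1.51), with Ifit3 at 0.107, and 5 of 6 MHC class II genes were (median -1.18). Alternative activation genes went both ways (median -0.90), with Arg1 higher and 3 of 7 lower, Retnla (0.057) and Il10 (0.115) among them. Lower levels were also read for Timd4 (0.021, 0.007 to 0.049), Tnfsf9 (0.135) and Ptgs2 (0.146). Matrix remodelling genes had 5 of 8 higher and 1 lower (median 1.73), oxidative stress genes 3 of 7 higher (0.87), glycolysis genes 3 of 10 higher and 1 lower (0.84), and lipid uptake receptors 2 of 5 higher and 1 lower (0.91). No member of the fatty acid oxidation (median 0.48) or oxidative phosphorylation list (0.37) reached a ratio of 2. Medians for the unfolded protein response (0.14) and phagocytosis lists (0.16) lay at percentiles 64.6 and 80.4. Apoe stood at 46451 against 27605 (1.68, 1.67 to 1.69) and Ldlr at 1.04 against 0.657, too low to compare. Trem2 (3.26) and Cd9 (4.66) are markers by which the foamy-like pool was named, so their ratios are no finding.

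The nearest comparison between the libraries set macrophages of the foam library (388 cells) against the foamy-like macrophages of the CD45+ library (236 cells). Across 1662 genes, which are not independent of one another, the mean profile of the foam library macrophages had its highest correlation with that foamy-like cluster (Pearson r 0.941), and 0.761 or less with each of the other 16 CD45+ clusters. Lipid droplet genes were at like levels. None of 6 lipid droplet genes differed by 2-fold and their median log2 ratio was 0.05 (-0.08 to 0.16; 0.46 at Leiden resolution 0.6), with Plin2 at 1173 against 1267 CPM. The cholesterol efflux and LXR target list had a median of 0.18 (0.14 to 0.27), with Lpl 2-fold higher (1971 against 941, ratio 2.09, 2.02 to 2.17) and Abca1, the cholesterol exporter, at 399 against 351. Lysosomal genes were somewhat higher (median 0.39, 0.37 to 0.41), with 2 of 20 at least 2-fold higher, Ctsl (3.46, 3.36 to 3.56) and Atp6v0d2 (2.73, 2.51 to 2.97). Cd5l, a scavenger protein of macrophages, was higher (6.70, 6.20 to 7.25), as was Mfge8, a bridge to apoptotic cells (819 against 53.6), which stood at 594 in the other classes of the foam library.

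Inflammatory genes were lower in the foam library macrophages. Of 16 listed proinflammatory genes only 4 were measured, and all 4 were at least 2-fold lower. Their median was -1.93 (-2.10 to -1.75, below all 10000 random lists). Il1b stood at 36.02 against 234 CPM (0.154, 0.136 to 0.174) and Tnf at 14.2 against 63.0 (0.226, 0.183 to 0.278). With the strict filter the log2 ratio of Il1b was -1.65 in place of -2.70. None of the 4 reached the minimum of 50 CPM in the foam library macrophages, so all were measured through the CD45+ foamy-like cells. The direction of the 4, and the sign of their median, thus follow from that minimum. With a minimum of 20 CPM, which changes the genes measured, the median was -1.55. Of 12 chemokines 9 were lower (median -1.45), with Cxcl2 at 128 against 678, and 7 of 12 NF-kB feedback genes (-1.003), with Ier3 and Nfkbia among the lowest. MHC class II genes had 4 of 6 lower (-1.12), such as Cd74 at 5035 against 11350. The immediate early list was lower too, with a median of -0.73 and 2 of 13 members 2-fold lower, and Hspa1a stood at 64.2 against 329. Arg1 (3.02 against 86.5, a log2 ratio of -4.82 that was -0.69 without the cells with the most UMIs), Ccr2 (4.09 against 54.2), Clec4a1, Kdm6b, Cxcl1 and Cbr2 completed the lowest genes. The log2 ratio of Cbr2 was -1.81, and 0.86 once free RNA was subtracted, which can set a sum to 0. These values depend on cluster 10 of the foam library, in which Il1b stood at 485 CPM and Cd74 at 17802. It lost the macrophage name through monocyte markers, Ccr2 among them, so the low Ccr2 follows in part from the naming. A CD45+ cluster led by Ccr2 against the rest of its library kept the name. Cells outside the class included named monocyte-like cells only in the CD45+ library, so the naming rule acted unequally on the 2 libraries. With its cells counted as macrophages, an addition chosen after seeing the data, the proinflammatory median was -1.62 with 4 of 4 lower, Il1b was at 83.4 (ratio 0.356, 0.325 to 0.391), 7 of 12 chemokines and 4 of 12 NF-kB feedback genes were 2-fold lower, and 0 of 6 MHC class II genes were (median -0.77), while the log2 ratio of Ccr2 was -1.70 in place of -3.71. Medians were 0.39 for lipid uptake receptors, 0.12 for matrix remodelling, 0.18 for phagocytosis, 0.18 for oxidative stress, 0.06 for oxidative phosphorylation, -0.12 for fatty acid oxidation, -0.13 for glycolysis, -0.17 for the unfolded protein response and -0.62 for alternative activation, and 0.00 over the 2 measured interferon genes. Trem2 stood at 1789 against 1245 and Cd9 at 1171 against 884. Apoe was 1178-fold lower (1069 to 1302), a gene disrupted in these mice, and Ldlr, at 2.14 against 1.04, was too low to compare.

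**Figure D2:**
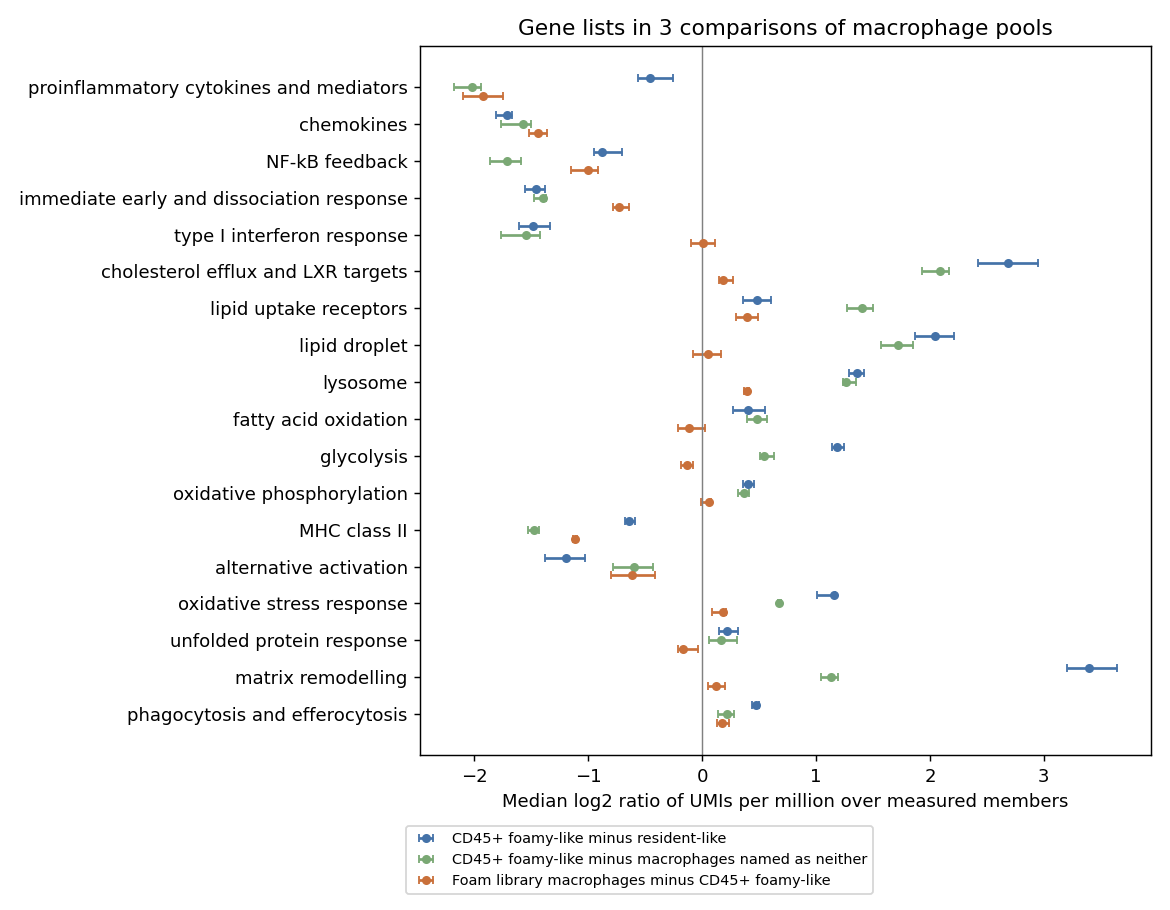
Median log2 ratio of pooled CPM over the measured members of each list (x axis) for each gene list (y axis) in 3 comparisons; points are medians and lines 95% intervals from Poisson redraws, which cover counting error only. The proinflammatory median was -0.46 against resident-like cells, -2.02 against the macrophages named as neither, and -1.93 between the foam library macrophages and the CD45+ foamy-like cells.

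The 12 genes with the highest log2 ratios in that comparison were Bgn, Lum, Serpina3n, Sod3, Col1a2, Dcn, Clu, Mgp, Col3a1, Rcan2, Sparc and Col1a1, among them 5 fibroblast markers (Lum, Col1a2, Dcn, Col3a1, Col1a1). All 12 stood higher still in the other classes of the foam library. Mgp, for example, was at 1609 CPM in macrophage-like cells and at 22449 in the other classes, against 12.2 in the CD45+ foamy-like cells, and Col1a1 at 82.5, 2488 and 0.777. With the strict cell filter Rcan2 had a log2 ratio of 5.84 in place of 6.89, and the other 11 genes stood from 0.25 for Dcn, in place of 7.31, to 3.18 for Clu, in place of 7.25. That filter also changed the reference pool: 280 CD45+ cells were foamy-like in place of 236, and no CD45+ cluster was named smooth muscle-like. Whether smooth muscle-like cells had joined the foamy-like pool was not tested directly. With the same foam library cells, Bgn fell from 9.07 to 1.00 here, but from 6.04 to 3.36 against all CD45+ macrophages. Each gene among the highest in both comparisons fell further here. Part of the fall thus lies in the foamy-like reference pool, and these lower ratios need not come from cell quality. Serpina3n had 0 UMIs in the CD45+ foamy-like cells and was at least 68.9-fold higher in the foam library. Its log2 ratio was 1.93 with the strict filter, against that changed reference.

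Set against all CD45+ macrophages, the foam library macrophages had lower inflammatory and higher lipid droplet lists. The proinflammatory median was -2.98 (-3.17 to -2.80), with 7 of 8 genes 2-fold lower, and the lipid droplet median 1.26 (1.20 to 1.32), with 4 of 6 higher. Without the 4 CD45+ clusters led by a marker of another class these were -2.79 and 1.13, and with cluster 10 counted as macrophages -2.88 and 1.42. Il1b was 26.3-fold lower (23.8 to 29.3) and Tnf 13.4-fold lower (11.4 to 15.9); with cluster 10, Il1b stood at 83.4 against 949 CPM (ratio 0.0879, 0.0823 to 0.0938) and Tnf at 15.5 against 191. Chemokines (-3.61), NF-kB feedback (-2.34), alternative activation (-2.33), immediate early (-2.10), MHC class II (-2.07) and interferon genes (-1.95, 8 of 9 genes 2-fold lower; with cluster 10 -1.21, 6 of 9) had negative medians. Efflux (1.89), lysosome (1.55), matrix remodelling (1.09), oxidative stress (1.07), lipid uptake (0.76), glycolysis (0.59), phagocytosis (0.47), fatty acid oxidation (0.37) and oxidative phosphorylation lists (0.33) had positive ones, and the unfolded protein response was at -0.05. The lowest genes were Retnla (0.097 against 681 CPM), Cd209f, Cd163, Ccl24, Timd4, Cxcl10, Lyve1, Vsig4 and Mgl2, and 3 genes with 0 UMIs, Cxcl13 (at least 247-fold lower), Cd209g (at least 246-fold) and Cd209d (at least 191-fold). Lyve1 and Cd163 are markers of resident-like cells, which were 1510 of the 3193 CD45+ macrophages and 0 of the 388 foam library ones. Retnla, Cd209d, Cd209f, Cd209g and Vsig4 were among the leading genes of a resident-like CD45+ cluster. The pools thus differed in their macrophage subsets. Mgl2 is a dendritic cell marker, so its level can follow in part from the naming of classes. With cluster 10 the log2 ratios of most of these genes were nearer 0, among them Cd163 at -5.41 in place of -8.82, Lyve1 at -5.28 in place of -7.84, Cd209f at -5.59 in place of -10.38 and Retnla at -9.07 in place of -12.19, and Cd209g (-6.78) and Cd209d (-6.87) had UMIs. The highest were Serpina3n, Lum, Clu, Col3a1, Sod3, Eln, Mgp, Rcan2, Col1a1, Col1a2, Tm4sf1 and Bgn, again all 12 at a higher level in the other classes of the foam library. Once free RNA was subtracted the log2 ratios of Col1a1 (6.31) and Tm4sf1 (6.04) were -2.00 and -0.77, and with the strict filter 3.39 and 3.95. The subtraction can set a sum to 0, so the negative values may rest on few or no UMIs and show no reversal. With the strict filter no CD45+ cluster was named smooth muscle-like, so the CD45+ reference may have changed too. Trem2 (3.67) and Cd9 (4.25) were higher, and Ldlr, with 22 UMIs in each pool, stood at 2.14 against 0.704 CPM (3.04, 1.61 to 5.76), too low to count as measured.

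Within the foam library, macrophage-like cells were set against smooth muscle-like cells (148 cells). All 20 lysosomal genes (median 2.84), all 6 MHC class II genes (3.25) and 10 of 11 chemokines (2.59) were at least 2-fold higher in macrophage-like cells, as were 5 of 7 lipid droplet genes (1.97), 6 of 9 efflux genes (2.35), 4 of 6 lipid uptake receptors (2.86) and 6 of 11 phagocytosis genes (3.26). The highest log2 ratios were those of Ifi204, Tnfaip2, Bcl2a1b, Atp6v0d2, Il1rn, Cd5l, Ctss, C3ar1, Fcgr2b, Msr1, Abcg1 and Cd74, from 4.23 for Ifi204 (ratio of CPM 20.1, 9.71 to 50.3) to 3.57 for Cd74 (11.9, 11.1 to 12.7). Smooth muscle-like cells had more Vldlr, a lipoprotein receptor (107 against 1.17 CPM), Egr1, Hspa1b, Cxcl1, Timp1, Sdc4, Ptgs2, Fn1, Mgll, Ier3, Thbs1 and Mmp2. Only Ptgs2 of the proinflammatory list was measured, so its median (-2.47) is that of 1 gene and was 3.44 with a minimum of 20 CPM and 1.14 with cluster 10; Il1b stood at 36.02 against 3.07 and Tnf at 14.2 against 0.878, from 7 and 2 UMIs in smooth muscle-like cells and below the minimum. Medians of the other lists were 3.16 for 2 interferon genes, 1.58 for alternative activation, 1.47 for oxidative stress, 0.59 for fatty acid oxidation, 0.54 for glycolysis, 0.25 for oxidative phosphorylation, 0.15 for the unfolded protein response, -0.35 for NF-kB feedback, -0.68 for matrix remodelling and -0.94 for immediate early genes. The NF-kB median changed sign under 4 alternatives. Trem2 and Cd9 had ratios of 11.1 (10.04 to 12.4) and 1.74 (1.65 to 1.83), while Apoe, at 39.4 against 15.4 CPM, and Ldlr, at 2.14 against 9.22, were too low to compare.

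Macrophage transcripts were detected in cells of other classes in the foam library. The complement genes C1qa, C1qb and C1qc, made by macrophages, stood in smooth muscle-like cells at 8.24%, 8.61% and 7.42% of their macrophage level, and in endothelial-like plus mesothelial-like cells at 7.93%, 8.34% and 6.87%. Set against their level over all cells of the library, these complement genes together stood at 11.7% in those classes. In the CD45+ library that value was 7.59% in conventional DC1-like plus smooth muscle-like cells, so ratios there stand on a background too. Over 20 macrophage and foamy markers the median was 8.90% in smooth muscle-like and 8.83% in the endothelial-like and mesothelial-like cells, where Cd9 stood at 98.7% and Fabp4 at 45.1%. Ratios between macrophage-like and smooth muscle-like cells, such as 11.1 for Trem2, stand on this background. The median log2 ratio over all measured genes in that comparison was -0.13.

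**Figure D3:**
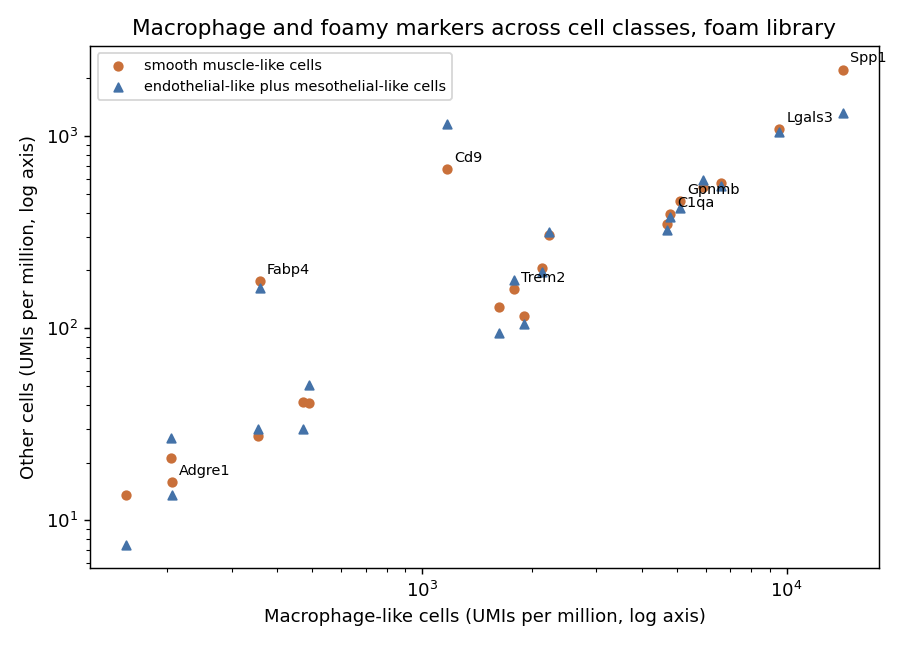
Level of 20 macrophage and foamy markers in macrophage-like cells (x axis, CPM, log axis) and in smooth muscle-like cells (circles) or endothelial-like plus mesothelial-like cells (triangles; y axis, CPM, log axis) of the foam library. Each point is 1 gene; most lie near 8.90% of the macrophage level in both, while Cd9 (57.6%) and Fabp4 (49.3%) lie higher.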

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

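The tests of free RNA, of macrophage gene expression by smooth muscle cells and of doublets in macrophages were chosen after the results they measure had been seen; the tests of depth, of the dissociation response and of doublets in smooth muscle-like cells were written before.

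Signals appeared in cells that none of the main comparisons used. In the CD45+ library 30 cells were smooth muscle-like (0.801%, 0.541% to 1.14%), with Acta2 at 16812 CPM and Ptprc, the gene of CD45, at 56.3. In the foam library, unnamed cluster 7 had 64 cells with fibroblast and chondrocyte markers, among them Ibsp at 1275, Comp at 677, Col2a1 at 241 and Sox9 at 135 CPM, beside Spp1 at 26599. Unnamed cluster 10 had 81 cells with all 12 macrophage markers high, Ccr2 at 123, Il1b at 485, Cd74 at 17802 and the T cell gene Cd3g at 64.3 CPM. A further 56 foam library barcodes (6.92%) exceeded the mitochondrial limit and were left out, with a median of 7782.5 UMIs, Acta2 at 8696 CPM and C1qa at 837.

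Smooth muscle transcripts in macrophages of the foam library were the first pattern weighed. Their markers stood in macrophage-like cells at 0.858 times the level in endothelial-like plus mesothelial-like cells (median of 8 genes, 0.405 to 2.34), as free RNA needs, although macrophage levels as a share of smooth muscle levels ran from 0.688% for Tagln to 4.39% for Tpm2, and the profile of the free RNA was not measured. Doublets would put the signal in few cells, but the tenth of macrophage-like cells with the largest share held 12.1% of these UMIs (10.3% to 13.6%), against 12.4% if all cells had one rate. The median log2 ratio to CD45+ macrophages was 5.12 and, after thinning, 5.58. Thinning kept each cell's class and, on average, its gene proportions, so it could not decide whether depth was a cause. No biological explanation was tested.

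Macrophage transcripts in smooth muscle-like cells of the foam library were the second. Over 20 macrophage and foamy markers the median log2 ratio of smooth muscle-like to endothelial-like plus mesothelial-like cells was 0.056 (genes from -0.78 to 0.75), which free RNA from macrophages needs. The same 0.056 argues against these markers as a set being switched on in the cells still named smooth muscle-like. Smooth muscle cells that had switched them on could have been given another name or none, so the value says nothing of them. The reference was only 20 endothelial-like and 8 mesothelial-like cells. Single genes such as Spp1 (15.6% of the macrophage level in smooth muscle-like and 9.24% in the other cells) and Cd9 (57.6% and 98.7%) stay open. Doublets could not be decided: the tenth of cells with the largest share held 27.4% of the UMIs (15.01% to 39.6%), against 10.8% at one rate.

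The lower proinflammatory list in foamy-like than in other CD45+ macrophages was the third. Among cells matched in 3 bands on the immediate early list, the mean of the medians was -0.95 against -1.54 unmatched, and the bands gave -1.31, -0.95 and -0.58, the last with 11 foamy-like cells. A dissociation response in the other macrophages cannot be told apart from a difference present in the tissue, since part of the value was lost and part remained. Thinning left -1.52. It kept each cell's class and, on average, its gene proportions, so it could not decide whether depth was a cause. A biological difference of lipid-laden cells stays open and was not tested apart from digestion.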

How the results depend on the processing

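Chosen after seeing the data were the settings without the clusters led by another class, with cluster 10 of the foam library, with free RNA subtracted, without the cells with the most UMIs, without proliferating clusters, and the split into resident-like and other references; the rest were planned. Across all settings run, the sign was kept by 17 of 18 list medians and 28 of 29 named genes for foamy-like against other CD45+ macrophages, 17 of 18 and 27 of 29 for the foam library against all CD45+ macrophages, 12 of 18 and 26 of 27 against the CD45+ foamy-like cells, and 16 of 18 and 26 of 26 for macrophage-like against smooth muscle-like cells. The last comparison was not run with the strict filter, which left 19 smooth muscle-like cells, fewer than the 20 required. The loose filter is 200 genes and 20% mitochondrial, the strict one 1000 genes and 5%. Ratios of genes with few UMIs, such as Ldlr, are limited by depth. Beyond counting error, settings moved 146 of 342 values of list medians (95 nearer 0, 51 further from 0) and 240 of 551 values of named genes (119 and 121) for foamy-like against other CD45+ macrophages, 125 of 306 (69 and 56) and 117 of 490 (96 and 21) for the foam library against all CD45+ macrophages, 105 of 306 (43 and 62) and 121 of 454 (75 and 46) against the CD45+ foamy-like cells, and 67 of 287 (26 and 41) and 84 of 416 (34 and 50) for macrophage-like against smooth muscle-like cells. Large ones among them, such as efflux genes from 2.30 to 0.41 at Leiden resolution 0.6 and Arg1 from 4.92 to 0.82 without the cells with the most UMIs in the first comparison, and Dcn from 7.31 to 0.25 with the strict filter in the third, are given in the report. Below, moved values are given only for shares and for the proinflammatory and lipid droplet lists, and, for any list or named gene, values of the opposite sign where the interval of the main value excludes 0; the lipid droplet, interferon, fatty acid oxidation and oxidative phosphorylation medians of the third comparison also changed sign, but their main intervals include 0; a minimum changes which genes are measured and cluster settings change which cells are pooled, and otherwise the cause was not tested.

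The macrophage-like share of the CD45+ library was 46.0% without the clusters led by another class. The macrophage-like share of the foam library was 46.9% with the loose filter, 60.7% with the strict filter, 44.2% with predicted doublets kept, 46.6% at Leiden resolution 0.6, 45.9% with list genes kept for clustering, 43.4% with another clustering seed, 56.5% without the cells with the most UMIs, 62.5% with cluster 10. The smooth muscle-like share of the foam library was 3.18% with the strict filter. The foamy-like share of macrophages in the CD45+ library was 10.7% with the loose filter, 9.06% with the strict filter, 16.3% at Leiden resolution 0.6, 10.4% with another clustering seed, 13.7% without the clusters led by another class.

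For foamy-like against other CD45+ macrophages, the median of proinflammatory genes was -1.37 with each cell weighted equally, -1.30 with a minimum of 20 CPM, -1.75 with free RNA subtracted, -1.41 with the loose filter, -1.83 with the strict filter, -0.84 at Leiden resolution 0.6, -2.10 at Leiden resolution 1.6, -1.30 without the cells with the most UMIs, -0.46 against resident-like macrophages only, -2.02 against the macrophages named as neither. Lipid droplet genes had a median of 1.07 with a minimum of 20 CPM, 1.51 with thinned cells, 1.69 with the loose filter, 1.41 at Leiden resolution 0.6, 1.35 without the cells with the most UMIs, 2.04 against resident-like macrophages only and phagocytosis genes had -0.018 at Leiden resolution 0.6. Il1b was at 0.30 against resident-like macrophages only.

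For the foam library against all CD45+ macrophages, the median of lipid droplet genes was 1.18 with median-ratio scaling, 1.70 with each cell weighted equally, 1.54 with a minimum of 100 CPM, 1.77 with thinned cells, 1.13 without the clusters led by another class, 1.42 with cluster 10, 1.56 without the cells with the most UMIs. Proinflammatory genes had a median of -2.64 with a minimum of 20 CPM, -3.41 with a minimum of 100 CPM, -3.19 with thinned cells, -2.79 without the clusters led by another class, -3.24 with free RNA subtracted, -3.30 with list genes kept for clustering. Col1a1 was at -2.00 with free RNA subtracted and Tm4sf1 at -0.77 with free RNA subtracted, where a sum can be set to 0. Unfolded protein response genes had 0.0060 with the loose filter.

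For foam library macrophages against CD45+ foamy-like cells, the median of proinflammatory genes was -1.55 with a minimum of 20 CPM, -1.71 with a minimum of 100 CPM, -2.36 with thinned cells, -1.62 with cluster 10, -2.14 with the loose filter, -1.64 with the strict filter, -2.68 at Leiden resolution 0.6, -1.42 at Leiden resolution 1.6. Matrix remodelling genes had -0.11 with free RNA subtracted. Cbr2 was at 0.86 with free RNA subtracted, with the same limit of sums set to 0. Lipid droplet genes had a median of 0.17 with the loose filter, 0.46 at Leiden resolution 0.6, 0.16 with another clustering seed and glycolysis genes 0.061 at Leiden resolution 0.6, 0.023 with another clustering seed.

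For macrophage-like against smooth muscle-like cells, the median of NF-kB feedback was 0.043 with each cell weighted equally, 0.019 with a minimum of 20 CPM, 1.70 with a minimum of 100 CPM, 0.18 with thinned cells. Proinflammatory genes had a median of 3.44 with a minimum of 20 CPM, -2.98 with thinned cells, -3.10 with free RNA subtracted, 1.14 with cluster 10, -2.84 with list genes kept for clustering. Lipid droplet genes had a median of 2.66 with a minimum of 100 CPM, 1.57 with thinned cells, 2.40 with free RNA subtracted.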

Other observations

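The comparison of the CD45+ foamy-like cells with each part of the other macrophages, chosen after seeing the data, held further differences. Against resident-like macrophages, 8 of 10 glycolysis genes (median log2 ratio 1.19) and 6 of 8 matrix remodelling genes (3.40) were at least 2-fold higher, against 1 of 10 (0.55) and 4 of 8 (1.13) when the macrophages named as neither were the reference. MHC class II genes had 0 of 6 members 2-fold lower against resident-like cells (-0.64) and 6 of 6 against the others (-1.48).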
